A study of Mus musculus with 4 samples.

How the data were processed

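Total RNA, 1 ug per sample, of pooled corpus callosum and cortex from mice at postnatal day 15 was made into Illumina TruSeq libraries, per the labels' protocols. The labels put 2 samples in the Pdgfra-creER;SmoM2 group and 2 in the wild type group, with tamoxifen given from postnatal day 5 to 7. Each column of the table was tied to its sample by the pairing in the series text.

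The deposited table lists 5282 genes. It was filtered by the authors: the highest unadjusted p-value in it is 0.049997, so each listed gene was chosen for its difference on these same samples. RSEM, DESeq2 and the build GRCm38.p6 are named without versions or roles, per the submitters' processing notes. For each sample the authors' deposited table gives an expression level with 2 decimals, scaled for gene length and library size as judged from the values; whether it is TPM or FPKM is not stated. The table also holds the authors' group means, a fold change as a ratio of SmoM2 over WT, its log2 value, a p-value and an adjusted p-value. The authors' adjusted p-value equals p times 57010 over the rank of p for 5273 of 5282 genes, 99.8%, within an absolute tolerance of 1e-06. A tolerance of that size says little for adjusted p-values below it. The formula is that of Benjamini and Hochberg over 57010 tests without its last step. With that step the number at an adjusted p of at most 0.05 is also 1968. The authors' fold change and the ratio of the levels had the same sign for 4772 of the 4845 genes with a mean level of at least 1, 98.5%, and another sign for 73, of which 14 were called. Of the gene identifiers, 5226 were found in the GENCODE M21 annotation of GRCm38 and 56 were not; coordinates come from that annotation. 4807 listed genes were protein-coding and 117 were pseudogenes, whose levels may share reads with their parents. 129 genes were listed at 0 in both samples of a group, which in a table without counts can be a failed estimate; no fold is given for those.

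The design was fixed before the data were examined, for either count or level tables. Since the unit turned out to be a level in a table of selected genes, the branch written for that case was used. A gene was called at an adjusted p of at most 0.05 in the authors' deposited table, and no test across genes is a result of its own. For each listed gene the mean and SD over the 2 samples of a group were computed from the levels. limma 3.58.1 in R 4.3.3 was run on log2(level + 1), with a mean-variance trend, for the 4845 genes with a mean level of at least 1, and gave the log2 differences and standard errors. These are on the log2(level + 1) scale, which understates the change of low genes. Its adjusted p was taken over 57010 tests. This is a recalculation on a selected list. The steps were tested on simulated data for the SmoM2 against WT comparison, with 4845 genes, 200 of them changed, and a noise SD of 0.15. It recovered 49.3% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2, with 1 false call among 167. The simulation adjusted over its 4845 tests, not 57010, and gave every gene the same noise SD. Its rates therefore do not carry over to the recalculation.

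33 gene lists, with 484 genes counted once, were fixed before the data were examined, for hedgehog components and targets, cholesterol synthesis, regulation and efflux, lipid synthesis, 3 oligodendrocyte stages, differentiation inhibitors, the cell cycle, other cell types, adjoining regions, blood, ribosomal, mitochondrial, stress and sex-linked genes. For each list the members with a row were counted by direction, and Fisher's exact test set their direction against that of all other listed genes. The test treats genes as independent, which genes measured in the same libraries are not. Tests were two-tailed, with Benjamini-Hochberg adjustment over the 33 lists. Members without a row could not be counted. Counts adjusted over the list alone start from p-values that are all at most 0.05, so they are high by construction. 6 further lists were written after the data were seen and are used in the closing section only. Tests that compare a list's mean with all genes were not run, since the table lacks the unselected genes.

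Genes were named by a rule fixed beforehand: Smo, Pdgfra and hedgehog targets such as Gli1, Ptch1 and Hhip where listed; up to 3 called members of each list with the largest absolute log2 fold change and no overlap between groups, or else the member of highest level; the 8 highest and 8 lowest called genes with a usual symbol, no overlap and a level of at least 5 in the higher group; and the 4 called genes of highest level. It named 94 genes, some of which are not reported here. Other list members in the text, among them Mbp, Myrf, Olig2, Sc5d, Idi1, Srebf2, Scap, Fasn and Top2a, were chosen after their values were seen.

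The alternatives were pseudocounts of 0.1 and 5, quantile normalization, equal medians, no filter on low levels, a minimum mean level of 5, totals without mitochondrial and globin genes, the replicate number as a block, each library left out in turn, and other thresholds. Alternatives written for count tables (other size factors, upper-quartile scaling, DESeq2's test and voom) were not run because there are no counts. Precision is limited by 2 samples per group. The median absolute log2 difference between the samples of a group was 0.13 for SmoM2 and 0.16 for WT. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and figures.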

Results

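RNA was measured in pooled corpus callosum and cortex of mice at postnatal day 15. Corpus callosum is a white matter tract rich in oligodendrocytes, the cells that form myelin. 2 samples came from Pdgfra-creER;SmoM2 mice and 2 from wild type (WT) mice, and all 4 received tamoxifen from postnatal day 5 to 7. SmoM2 is a constitutively active form of Smoothened, the membrane protein that passes on the hedgehog signal, and Pdgfra-creER is a tamoxifen-inducible recombinase under the control of Pdgfra, a gene of oligodendrocyte precursor cells and of fibroblasts. The values analysed here are a table of 5282 genes that the authors selected by p-value, with an expression level for each sample; every listed gene has an unadjusted p of at most 0.05. The level is scaled for gene length and library size, and whether it is TPM or FPKM is not stated. Depth per sample is unknown, since the table holds no read counts. The levels of the listed genes summed to between 469062 and 512833 per sample. The labels do not say whether samples were separate animals, so no p-value here speaks for variation between animals. "Rose", "fell" and "changed" are used below for genes at an adjusted p of at most 0.05 in the authors' deposited table. A "list" is a set of genes fixed before the data were examined, and its listed members are those with a row in the table.

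The comparison asks which genes differ in expression when Smoothened signalling is switched on in Pdgfra-lineage cells, with myelin and cholesterol as the subjects named by the study's title. Smo itself, the gene altered by design, was higher in both SmoM2 samples, at 10.73 and 10.96, than in both WT samples, at 7.12 and 5.75. Its level averaged 10.8 ± 0.163 in SmoM2 and 6.44 ± 0.969 in WT (SD, n = 2 each), a log2 difference of 0.68 ± 0.16 (SE, limma). The authors' deposited table gives Smo (ENSMUSG00000001761, chromosome 6, 29735503 to 29761365, GRCm38) a log2 fold change of 0.65 and an adjusted p of 0.00146. Whether reads from the SmoM2 allele count towards Smo is not given in the sources used here. Gli1, Ptch1 and Hhip, transcripts that hedgehog signalling induces, and Pdgfra had no row in the table and were not analysed here. Of 17 hedgehog pathway components, 4 had a row, and Smo was the member that rose. Sufu, Gas1 and Disp1 had log2 fold changes of 0.41, 0.48 and 0.54 in the authors' deposited table and did not pass. Of 19 hedgehog target genes, 6 had a row and 5 rose, namely Mycn, Ccnd1, Foxc1, Foxc2 and Spp1. The other 13 targets, Gli1, Ptch1 and Hhip among them, had no row. Foxc1 and Foxc2 are also genes of meningeal fibroblasts, and Spp1 is also in the reactive myeloid list. Without SmoM2 replicate 1 the log2 difference went from 0.48 to 0.20 for Foxc1 and from 0.98 to 0.44 for Spp1 (limma). Ccnd1, which encodes cyclin D1, averaged 22.9 ± 0.962 in SmoM2 and 15.6 ± 1.41 in WT (SD, n = 2 each), and Mycn averaged 18.2 ± 0.983 and 12.7 ± 0.0919. Nkx6-2, a transcription factor gene of oligodendrocytes, had a log2 fold change of -0.76 at an adjusted p of 0.099 in the authors' deposited table. All 4 listed components and 5 of the 6 targets were higher, and the adjusted p for direction was 0.252 for components and 0.355 for targets (Fisher's exact test). With all 4 higher the unadjusted p of the component test was 0.128, so it could not pass in that direction. Here and below, a direction test that misses the threshold leaves open whether a list leans.

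Genes of mature oligodendrocytes and myelin fell in SmoM2. Of 26 genes in the list, 24 had a row, all 24 were lower and 23 fell, whereas 46.8% of all listed genes were lower. The median log2 fold change of the 24 was -1.002 in the authors' deposited table, with a range of -2.03 to -0.47. Mal, which encodes a myelin proteolipid, averaged 24.4 ± 2.58 in SmoM2 and 93.6 ± 8.27 in WT (SD, n = 2 each), a log2 difference of -1.90 ± 0.12 (SE, limma). Opalin, an oligodendrocyte membrane protein gene, averaged 4.31 ± 0.955 and 15.6 ± 0.445, and Ermn averaged 2.76 ± 0.00707 and 8.62 ± 0.566. Mbp, which encodes myelin basic protein, averaged 2102 ± 207 in SmoM2 and 3764 ± 336 in WT, a log2 difference of -0.84 ± 0.13 (SE, limma). Adjusted p-values in the authors' deposited table were 2.04e-67 for Mal and 1.57e-32 for Mbp. In GRCm38, Mal lies on chromosome 2 from 127633226 to 127656695 and Mbp on chromosome 18 from 82475146 to 82585637. Myrf, the transcription factor that drives myelin gene expression, averaged 10.3 ± 1.75 in SmoM2 and 14.6 ± 1.10 in WT. Gjb1 was lower in both SmoM2 samples but did not pass, at an adjusted p of 0.0785 in the authors' deposited table, and Aspa passed although its groups overlapped. The limma log2 difference of Aspa went from -0.34 to 0.13 without SmoM2 replicate 1 and to -0.11 without WT replicate 2, and that of Myrf from -0.47 to -0.31 without SmoM2 replicate 1. Adjusted over the list alone, the authors' p-values passed for all 24. The direction of the list differed from that of the other listed genes (Fisher's exact test, adjusted p = 3.86e-07). Genes of a list can move together in the same libraries. This p-value, like those of the other lists, therefore does not measure spread between samples. Leaving out any one library kept the median of the list's log2 differences between -0.96 and -0.74, with adjusted p from 5.85e-08 to 8.88e-06.

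**Figure D1:**
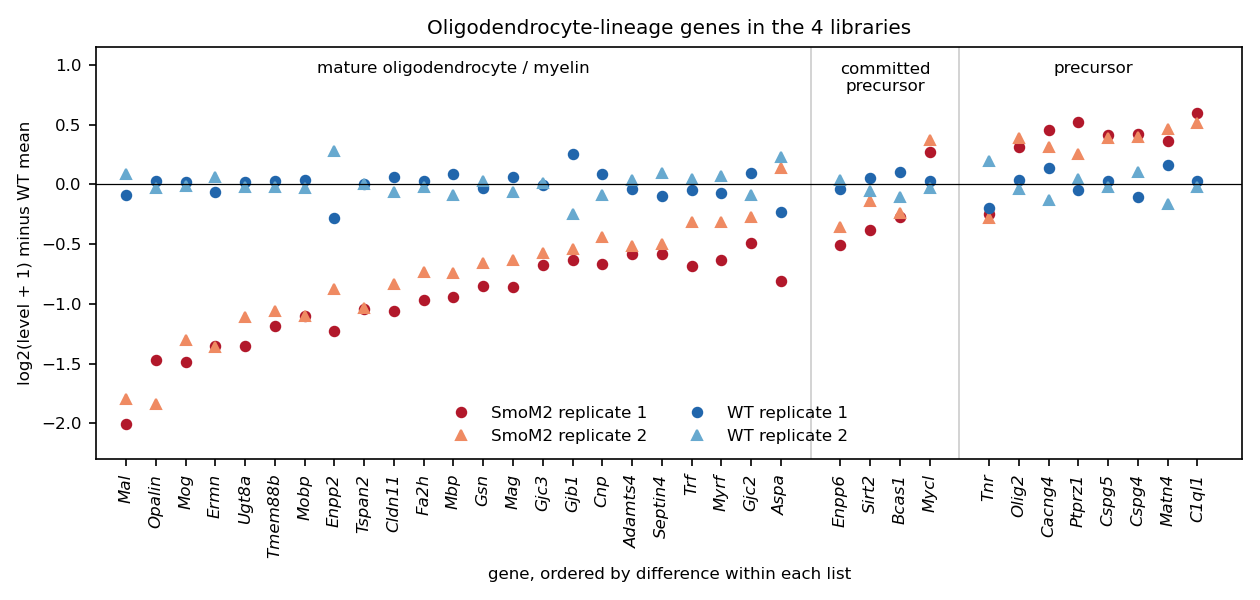
Level of listed oligodendrocyte-lineage genes in the 4 libraries, as log2(level + 1) minus the mean of the WT libraries (vertical axis), with genes along the horizontal axis in 3 lists. Each point is a library; all myelin genes shown except Aspa have both SmoM2 libraries below both WT libraries, and 7 of the 8 precursor genes have them above.

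Among earlier stages of the lineage, listed precursor genes were mostly higher and listed committed precursor genes mostly lower, and neither list passed its direction test. Of 19 oligodendrocyte precursor genes, 8 had a row and 7 of these were higher in SmoM2, with a median log2 fold change of 0.33 in the authors' deposited table. Cspg4, which encodes the NG2 proteoglycan, Ptprz1 and Cspg5 rose, and Tnr fell. Cspg4 averaged 10.3 ± 0.156 in SmoM2 and 7.56 ± 0.856 in WT (SD, n = 2 each), and Ptprz1 averaged 71.1 ± 9.62 and 53.9 ± 2.42. Olig2, Cacng4, Matn4 and C1ql1 were higher in both SmoM2 samples and did not pass, with log2 differences of 0.35 ± 0.10 for Olig2 and 0.55 ± 0.12 for C1ql1 (SE, limma). Of 14 genes of committed precursors, the stage between precursor and myelinating cell, 4 had a row. Enpp6, Sirt2 and Bcas1 fell, with Enpp6 at 8.02 ± 0.665 in SmoM2 and 11.1 ± 0.438 in WT, and Mycl had a log2 fold change of 0.22 in the authors' deposited table without passing. By Fisher's exact test the adjusted p for direction was 0.205 for the precursor list and 0.476 for the committed list. Adjusted over the list alone, the authors' p-values passed for 7 of the 8 precursor genes and 3 of the 4 committed genes. The list written for differentiation inhibitors of the Notch, BMP and Wnt pathways had 11 of 20 members in the table, of which 10 were higher and 5 rose. It mixes pathway genes of different roles, antagonists among them. A rise of its members therefore does not show a stronger block of differentiation. Bmp6 averaged 5.48 ± 0.757 in SmoM2 and 1.76 ± 0.424 in WT, and Hes5, a Notch effector, averaged 42.5 ± 4.45 and 23.4 ± 2.77. Notch1, Nkd1 and Apcdd1 rose too, and Id2 fell, from 219 ± 13.3 in WT to 124 ± 44.0 in SmoM2. Some of these log2 differences depended on a library (limma). Without SmoM2 replicate 1, Ptprz1 went from 0.39 to 0.25, Sirt2 from -0.26 to -0.14 and Notch1 from 0.44 to 0.26. Notch1 went to 0.25 and Bcas1 from -0.26 to -0.15 without WT replicate 1, Id2 from -0.86 to -0.49 without SmoM2 replicate 2, and Tnr from -0.27 to -0.07 without WT replicate 2. The direction of this list missed the threshold (Fisher's exact test, adjusted p = 0.0735).

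Genes of cholesterol synthesis moved in both directions, with more higher than lower. Of 20 enzymes, 11 had a row, 8 were higher and 3 lower in SmoM2. Mvd, Mvk and Dhcr7 rose, and Idi1 and Sc5d fell. Mvd, an enzyme of the mevalonate pathway, averaged 62.3 ± 2.79 in SmoM2 and 37.7 ± 4.16 in WT (SD, n = 2 each), a log2 difference of 0.72 ± 0.11 (SE, limma). Mvk, the mevalonate kinase gene, averaged 62.1 ± 6.14 and 41.5 ± 2.91, and Dhcr7, which encodes the last enzyme of the Kandutsch-Russell branch, averaged 59.1 ± 3.36 and 40.9 ± 0.332. Sc5d averaged 32.7 ± 3.54 in SmoM2 and 42.3 ± 0.198 in WT, and the groups of Idi1 overlapped, with a limma log2 difference of -0.33 that went to -0.18 without SmoM2 replicate 2 and to -0.13 without WT replicate 2. Sqle, Fdps, Pmvk and Tm7sf2 had log2 fold changes between 0.24 and 0.35 in the authors' deposited table and did not pass. Adjusted over the list alone, the authors' p-values passed for 9 of the 11. The direction test of the list missed the threshold (Fisher's exact test, adjusted p = 0.355).

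Regulators of cholesterol synthesis and uptake had 10 of 17 members in the table, of which 8 were higher and 6 rose, among them Srebf1, Srebf2, Scap, Lrp1 and Scarb1. Srebf2 encodes the main transcription factor of cholesterol synthesis genes, and Scap the protein that escorts it. Srebf2 averaged 121 ± 6.04 in SmoM2 and 87.7 ± 2.44 in WT (SD, n = 2 each), and Scap averaged 61.8 ± 5.48 and 43.6 ± 1.70. Log2 differences were 0.46 ± 0.09 for Srebf2 and 0.49 ± 0.11 for Scap (SE, limma), and that of Lrp1 went from 0.57 to 0.35 without WT replicate 1. Adjusted over the list alone, the authors' p-values passed for all 10, and Fisher's exact test gave an adjusted p of 0.252 for direction. Of 17 genes of cholesterol efflux and turnover, 2 had a row; Abcg4, a sterol transporter gene, rose and averaged 43.8 ± 2.98 in SmoM2 and 31.2 ± 2.72 in WT, and Nr1h2 did not pass. The direction test of this list gave an adjusted p of 0.571. Fatty acid and myelin lipid enzymes split: Fasn and Fads2 rose, while Ugt8a, Fa2h, Elovl7, Cers2 and Aspa fell, out of 11 with a row among 20. Fasn, the fatty acid synthase gene, averaged 193 ± 1.44 in SmoM2 and 133 ± 17.0 in WT. Ugt8a, which makes the galactolipids of myelin, averaged 24.1 ± 3.05 and 57.8 ± 1.32. Ugt8a, Fa2h and Aspa are also members of the myelin list, and the groups of Aspa overlapped. The direction of this list gave an adjusted p of 0.484 (Fisher's exact test).

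Cell cycle genes were higher in SmoM2 throughout the 12 of 26 list members with a row, although Cdk1 was the member that rose on its own. Cdk1, the mitotic kinase gene, averaged 12.3 ± 3.53 in SmoM2 and 5.61 ± 0.0141 in WT (SD, n = 2 each), and Top2a averaged 4.28 ± 0.665 and 2.23 ± 0.643 without passing. Adjusted over the list alone, 5 of the 12 passed by the authors' p-values. The direction of the list differed from the other listed genes (Fisher's exact test, adjusted p = 0.0101). That call ended without WT replicate 1, where the limma log2 difference of Mcm3, whose groups overlapped, went from 0.21 to -0.20. It also ended with genes of mean level of at least 5, at an adjusted p of 0.461 (Fisher's exact test). Only Cdk1, Mcm5 and Mcm6 remain there, too few for the test to pass. Across alternatives the adjusted p ran from 0.0116 to 0.461.

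**Figure D2:**
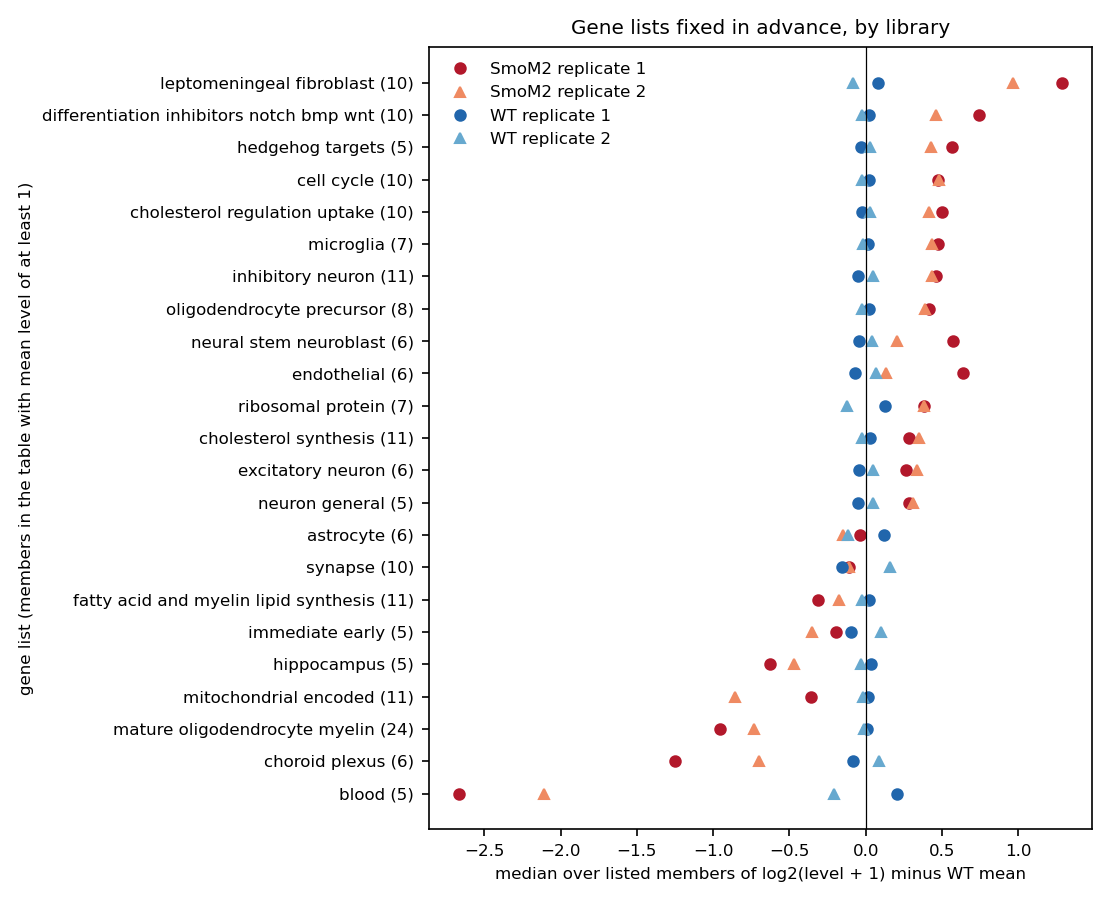
Median over the members of each list of log2(level + 1) minus the mean of the WT libraries (horizontal axis), for lists with at least 5 members of mean level of at least 1 (vertical axis, number in brackets). Each point is a library; the myelin list lies at -0.96 and -0.74 in the SmoM2 libraries and the leptomeningeal list at 1.29 and 0.96.

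Genes of leptomeningeal fibroblasts, the cells of the brain's inner coverings, rose in SmoM2. Of 12 in the list, 10 had a row and all 10 rose, with a median log2 fold change of 1.35 in the authors' deposited table. Col1a1, a fibrillar collagen gene, averaged 10.9 ± 4.91 in SmoM2 and 2.19 ± 0.219 in WT (SD, n = 2 each), Aldh1a2 averaged 9.25 ± 0.0636 and 3.02 ± 1.42, and Slc6a13 averaged 11.5 ± 2.74 and 3.56 ± 1.65. Col3a1 was among the 10 although its groups overlapped. Without WT replicate 2 the limma log2 difference of Ptgds went from 1.64 to 0.85. That of Dcn went from 0.65 to 0.41 without the same library and to 0.30 without SmoM2 replicate 2. Fn1 went from 0.73 to 0.41 without SmoM2 replicate 1 and to 0.43 without WT replicate 1. The list median stayed between 0.96 and 1.29 with a library left out. Fisher's exact test gave an adjusted p of 0.0252 for the direction of this list. Pericyte and smooth muscle genes were higher in all 5 of 9 with a row, and Vtn, Acta2 and Notch3 rose, with Vtn at 94.7 ± 11.7 in SmoM2 and 46.1 ± 13.9 in WT. Endothelial genes had 6 of 10 members in the table. Cdh5, Cldn5 and Kdr rose, with Cdh5 at 10.1 ± 2.59 in SmoM2 and 6.10 ± 0.735 in WT, and Slco1a4 and Ly6c1 fell. Endothelial rises were largest in SmoM2 replicate 1: without it the limma log2 differences went from 0.63 to 0.39 for Cdh5, from 0.64 to 0.41 for Cldn5 and from 0.44 to 0.16 for Kdr, and that of Col3a1 from 0.70 to 0.22. Ly6c1 went from -0.90 to -0.59 without SmoM2 replicate 2, and Notch3 from 0.77 to 0.34 without WT replicate 1. Adjusted p for direction was 0.195 for the pericyte list and 0.713 for the endothelial list.

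Choroid plexus genes were lower in all 7 of 10 members with a row, and 5 fell. Ttr, the transthyretin gene that choroid plexus expresses at high level, read 71.2 and 618 in the SmoM2 samples and 1203 and 1162 in the WT samples, so that on a log2 scale the SmoM2 samples differed from each other by more than the nearer of them did from WT. Folr1 read 1.85 and 6.01 against 10.89 and 10.96. Without SmoM2 replicate 1 the limma log2 difference of Ttr went from -2.48 to -0.93 and that of Folr1 from -1.42 to -0.77. The direction of the list differed from the other listed genes with the authors' fold changes (Fisher's exact test, adjusted p = 0.0406), but not with the signs of the levels (adjusted p = 0.0829). Without SmoM2 replicate 1 the adjusted p was 0.0656, without SmoM2 replicate 2 it was 0.0707 and without WT replicate 1 it was 0.111, within a range of 0.0354 to 0.461 over the alternatives. Of 10 genes of ciliated ependymal cells, 3 had a row and none passed. Blood genes fell in all 6 of 7 members with a row. Hba-a2, an alpha-globin gene, averaged 20.2 ± 4.35 in SmoM2 and 146.8 ± 25.4 in WT (SD, n = 2 each), a log2 difference of -2.80 ± 0.18 (SE, limma), and Hbb-bs averaged 41.9 ± 25.9 and 279 ± 89.2. Globin genes have near-identical copies, so their separate values are uncertain. The direction test gave an adjusted p of 0.0695 for blood genes and 0.663 for ependymal genes.

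**Figure D3:**
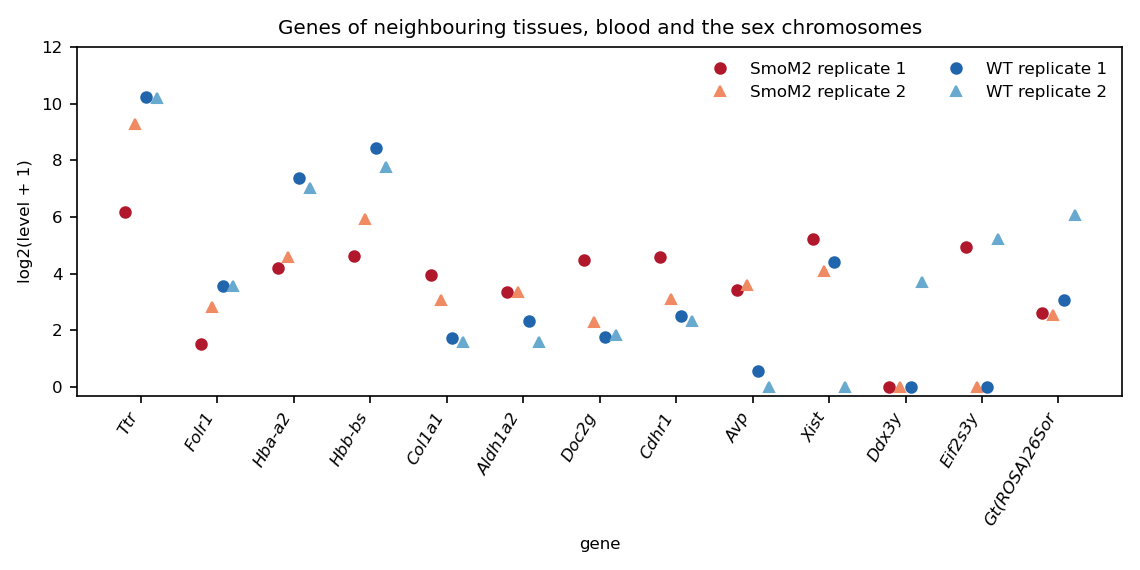
Level of genes of neighbouring tissues, blood and the sex chromosomes, and of Gt(ROSA)26Sor, in each of the 4 libraries, as log2(level + 1) (vertical axis), with genes along the horizontal axis and a point per library. Ttr differs between the SmoM2 libraries (71.2 and 618), Doc2g is high in SmoM2 replicate 1 alone (21.4), and Ddx3y is above 0 in WT replicate 2 alone (11.9).

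Neuronal genes moved both ways. Inhibitory neuron genes had 11 of 14 members in the table; Calb2, Sst, Slc32a1, Dlx1 and Reln rose, while Pvalb, Vip and Npy fell. Dlx1 read 41.4 and 23.8 in SmoM2 and 17.4 and 22.8 in WT, so its rise rests largely on SmoM2 replicate 1, where olfactory bulb genes, which include those of bulb interneurons, were highest too. Calb2, the calretinin gene, averaged 115 ± 10.7 in SmoM2 and 61.3 ± 12.4 in WT (SD, n = 2 each), and Pvalb, the parvalbumin gene, averaged 16.0 ± 5.04 and 29.2 ± 0.269. Among 13 general neuronal genes, 5 had a row; Tubb3 and Gap43, both of growing axons, rose, and Snap25 and Syt1, both of transmitter release, fell. Tubb3 averaged 1146 ± 29.5 in SmoM2 and 648 ± 30.8 in WT, and Snap25 averaged 1281 ± 5.49 and 1639 ± 218. Excitatory neuron genes had 6 of 14 members in the table, of which Cux2 rose and Neurod6 fell. Of 20 synapse genes, 10 had a row and 8 were lower; Grin2a and Homer1 were among the 3 that fell, and Shank1 and Shank3 rose. Grin2a, an NMDA receptor subunit gene, averaged 8.49 ± 0.361 in SmoM2 and 13.8 ± 3.73 in WT. Immediate early genes had 5 of 13 members in the table, and Egr4 rose while Egr1 and Npas4 fell, the latter with overlapping groups. Adjusted p for direction was 0.355 for inhibitory, 1.0 for general, 0.713 for excitatory, 0.195 for synapse and 0.353 for immediate early genes (Fisher's exact test). Neural stem cell and neuroblast genes had 6 of 12 members in the table, with Vim and Dcx rising, Prom1 falling and an adjusted p of 0.355 for direction. SmoM2 replicate 1 weighs on several of these: without it the limma log2 differences went from 0.67 to 0.29 for Vim, from 0.41 to 0.12 for Dcx, from 0.63 to 0.25 for Dlx1 and from -0.86 to -0.55 for Pvalb. WT replicate 2 weighs on others, and without it Grin2a went from -0.62 to -0.36, Homer1 from -0.33 to -0.18, Snap25 from -0.35 to -0.21, Syt1 from -0.20 to -0.08 and Npas4 from -0.67 to -0.29. Npas4 went to -0.33 without SmoM2 replicate 2, and Cux2 from 0.38 to 0.22 without WT replicate 1.

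Astrocyte genes split, with Gfap and Aqp4 rising and Slc1a2 and Gjb6 falling among 6 of 13 with a row, although the groups of Gjb6 overlapped. Gfap, the intermediate filament gene of astrocytes, averaged 188 ± 12.2 in SmoM2 and 131 ± 27.1 in WT (SD, n = 2 each), and Slc1a2, a glutamate transporter gene, averaged 307 ± 51.1 and 386 ± 44.1. Microglial genes had 7 of 14 members in the table, of which C1qb, C1qc and Fcrls rose and P2ry12 fell with overlapping groups. C1qc, a complement gene, averaged 82.1 ± 2.72 in SmoM2 and 53.2 ± 4.04 in WT. Of 16 reactive myeloid genes, 2 had a row and Spp1 rose. Interferon response genes were higher in all 5 of 15 with a row, and none passed; Bst2 averaged 12.1 ± 0.474 in SmoM2 and 6.16 ± 1.39 in WT. Direction tests gave adjusted p of 0.543 for astrocyte, 0.252 for microglial, 0.571 for reactive myeloid and 0.195 for interferon genes (Fisher's exact test). Markers of adjoining regions were included too. Of 9 striatal genes, 2 had a row, and Penk and Adora2a passed with overlapping groups. Hippocampal genes had 6 of 9 members in the table; Prox1 and Zbtb20 fell and Wfs1 rose. Adjusted p for direction was 0.571 for the striatal and 0.247 for the hippocampal list. Several limma log2 differences in these lists depended on a library. Without SmoM2 replicate 2, Slc1a2 went from -0.33 to -0.16, Zbtb20 from -0.37 to -0.18, P2ry12 from -0.20 to -0.05, Gjb6 from -0.22 to 0.09, Penk from 0.66 to 0.19 and Adora2a from 0.65 to -0.08. Leaving out WT replicate 2 brought Gfap from 0.53 to 0.32, Slc1a2 to -0.22, P2ry12 to -0.04, Penk to 0.05 and Adora2a to 0.12. Aqp4 went from 0.50 to 0.32 and Spp1 from 0.98 to 0.44 without SmoM2 replicate 1, and Gjb6 to -0.06 without WT replicate 1.

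Mitochondrially encoded genes had 11 of 13 members in the table, of which 9 fell and mt-Co2 rose. All genes in the table with a mitochondrial symbol, which include some outside this list, made up 16.0% and 13.0% of the listed level in the SmoM2 samples. In the WT samples they made up 20.3% and 20.7%. mt-Nd1 averaged 6696 ± 1077 in SmoM2 and 10785 ± 940.1 in WT (SD, n = 2 each), mt-Atp8 averaged 22876 ± 5221 and 35228 ± 4580, and these 2 were with mt-Co1 and mt-Cytb the 4 called genes of highest level. mt-Co1 and mt-Cytb were lower in both SmoM2 samples as deposited, and reversed after quantile normalization, to log2 differences of 0.047 and 0.073. That step gives genes of equal rank the same value in every library, so values near 0 are largely built in for the highest genes. Ribosomal protein genes were higher in all 7 of 20 with a row, and Rpl10a and Rplp0 rose, with Rpl10a at 495 ± 40.4 in SmoM2 and 304 ± 51.1 in WT. Of 16 stress and hypoxia genes, 3 had a row, and Rbm3 and Bnip3 fell. The direction tests gave adjusted p of 0.124 for mitochondrial, 0.0796 for ribosomal and 0.247 for stress genes (Fisher's exact test). After quantile normalization the median of the mitochondrial list went from -0.60 to -0.073 and its adjusted p to 0.815, while it passed without SmoM2 replicate 1, at 0.0326, and without WT replicate 2, at 0.0254. Limma log2 differences went from -0.64 to -0.40 for mt-Atp8 and from -0.48 to -0.26 for mt-Cytb without SmoM2 replicate 2, from 0.47 to 0.31 for mt-Co2 without WT replicate 1, from 0.59 to 0.37 for Rplp0 without WT replicate 2, and from -0.14 to -0.09 for Bnip3 without SmoM2 replicate 1. Of 6 sex-linked genes, 4 had a row. Xist, expressed from the inactive X chromosome, read 36.5 and 15.9 in the SmoM2 samples and 20.3 and 0 in the WT samples, while the Y-linked Ddx3y was above 0 in WT replicate 2 alone, at 11.9. Calls of Xist, Ddx3y and Uty rest on that library, without which their limma log2 differences went from 2.45 to 0.24, from -1.85 to 0 and from -1.14 to 0.03, and the list's direction gave an adjusted p of 0.476.

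Across the table, 1968 genes passed an adjusted p of at most 0.05, 1124 higher and 844 lower in SmoM2. The series text counts 2808 genes up and 2474 down and names a fold threshold, and the authors' deposited table holds 2808 higher and 2474 lower genes by p alone. Only 775 of the 5282 reached an absolute log2 fold change of 1, 462 higher and 313 lower, and the smallest listed was 0.15. Both criteria, adjusted p and fold, were met by 350 genes, 228 higher and 122 lower. The samples of the groups did not overlap in 1792 of the 1968, and in 4473 of all 5282 listed genes, 84.7%. Chance alone gives 33.3% for genes not chosen by their difference, which these were, so a high share is built in. Among called genes with a usual symbol, no overlap and a level of at least 5 in the higher group, the highest log2 fold changes were of Gdf1, Avp, Doc2g, Pgam1-ps2, Col1a1, Pin4-ps, Retnla and H19. Gdf1 read 20.1 and 13.5 in SmoM2 and was listed at 0 in both WT samples; its gene overlaps Cers1, so reads of these may not be told apart. Doc2g read 21.4 and 3.93 in SmoM2 and 2.44 and 2.55 in WT, and its log2 difference of 1.59 went to 0.50 without SmoM2 replicate 1 (limma). Avp, the vasopressin gene, read 9.76 and 11.22 in SmoM2 and 0.49 and 0 in WT. H19, an imprinted non-coding RNA, averaged 5.69 ± 0.771 in SmoM2 and 1.32 ± 0.106 in WT (SD, n = 2 each). Pgam1-ps2 and Pin4-ps are pseudogenes that share sequence with their parents, and their levels are uncertain; without WT replicate 1 their log2 differences went from 2.90 to 1.498 and from 2.53 to 0.86 (limma). Lowest under the same conditions were Commd1b, Etnppl, Hba-a2, Gt(ROSA)26Sor, Hbb-bs, Hbb-bt, Tmem52 and Mt2. Commd1b was listed at 0 in both SmoM2 samples and read 7.67 and 4.08 in WT. Etnppl, a gene of astrocytic lipid metabolism, read 0.25 and 0.15 in SmoM2 and 5.02 and 5.28 in WT, and Mt2, a metallothionein gene, averaged 109 ± 24.0 and 458 ± 54.1. Gt(ROSA)26Sor read 5.13 and 4.82 in SmoM2 and 7.43 and 66.3 in WT, and its log2 difference went from -1.995 to -0.50 without WT replicate 2 (limma).

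A recalculation from the levels with limma gave far fewer calls than the authors' p-values. Adjusted over the 57010 tests that the authors' adjusted p implies, 6 genes passed, namely Mal, Hba-a2, Gdf1 and 3 genes known by clone or model names. Leaving out WT replicate 1 gave 2, and leaving out SmoM2 replicate 1, SmoM2 replicate 2 or WT replicate 2 gave 0, with between 1486 and 1947 genes at an unadjusted p of at most 0.05 by limma. These genes were selected on the same samples, so this count describes the listed genes and is no test across all genes.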

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

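The added thresholds, the recalculation over the listed genes alone and the use of levels in place of the authors' fold changes were chosen after the data were seen; the other alternatives were planned. Against 1968 called genes, 1211 passed an adjusted p of at most 0.01, 775 an unadjusted p with an absolute log2 fold change of 1, and 350 an adjusted p with that fold. The rule named in the series text gave 775 genes, against 350 with the adjusted p and 5282 without the fold. The limma recalculation called 6 genes, 0 after quantile normalization and 0 without the filter, where 2764 and 2811 genes had an unadjusted p of at most 0.05. It called 5 to 6 under the pseudocounts, equal medians, the stricter filter and other totals, and 1619 when adjusted over the listed genes alone. The genes called were not always the same. Gdf1 lost its call with a pseudocount of 5 (limma, adjusted p = 0.0754) and with the stricter filter (0.0574). Hba-a2 lost its call with equal medians (limma, adjusted p = 0.0595). Leaving out a library gave 0 to 2 calls, where the remaining sample of a group is assumed to vary like the others. The median direction of 24 of the 25 lists with at least 5 listed members, and of 90 of the 92 named genes with a limma value, reversed in no alternative. Of 1885 called genes with a limma value, 616 had a log2 difference over 1.5 times smaller, or reversed, without some library, 341 of them without WT replicate 2, and 74 reversed. The hippocampal median was -0.85 by the authors' fold changes and -0.55 by levels, and turned to 0.020 by levels with a mean level of at least 5, where fewer genes remain. mt-Co1 and mt-Cytb turned to 0.047 and 0.073 after quantile normalization. The same step lowered the median of all listed genes from 0.25 to 0.13. It gives genes of equal rank the same value in every library. Both genes are among the called genes of highest level, so differences near 0 are largely built in and say little about expression. The cell cycle list lost its call with a mean level of at least 5, at a median of 0.45. Too few members remain there for the test to pass. It also lost its call without WT replicate 1, at a median of 0.52. Medians ran from 0.47 to 0.52 over left-out libraries. The choroid plexus list lost its call at -0.97 with levels in place of fold changes, -1.52 and -0.37 with pseudocounts of 0.1 and 5, -1.20 after quantile normalization, -1.07 with equal medians, -1.95 with the stricter filter, and -0.98 with other totals. It also lost its call without SmoM2 replicate 1, SmoM2 replicate 2 or WT replicate 1, but not without WT replicate 2 (adjusted p = 0.0439, Fisher's exact test), with medians of -1.25 to -0.70 over left-out libraries. Fewer of its members enter these tests; no other cause was tested. The mitochondrial list, not past the threshold in the report, passed without SmoM2 replicate 1 (adjusted p = 0.0326) and without WT replicate 2 (adjusted p = 0.0254, Fisher's exact test), with medians of -0.86 to -0.36 over left-out libraries. Its median was -0.073 after quantile normalization (adjusted p = 0.815, Fisher's exact test), a step that narrows differences among the genes of highest level. The myelin and leptomeningeal lists stayed past the threshold in every alternative run. With the replicate block, limma called 20 genes in place of 6. The labels do not say whether samples of the same number share more than that number. The deviations of same-numbered samples correlated at -0.09 across genes. Genes are not independent replicates, so this value cannot exclude a shared batch. Depth is unknown, so no limit from counting can be given.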

Other observations

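The 6 lists described in this part, and all of the tests in it, were chosen after the data were seen. Genes of young neurons were mostly higher in SmoM2: of 22 in the list, 17 had a row, 16 were higher and 15 rose. Tubb2b, a tubulin gene of growing neurons, averaged 737 ± 6.57 in SmoM2 and 314 ± 37.8 in WT (SD, n = 2 each), and Dpysl3, a gene of axon growth, averaged 159.9 ± 14.9 and 72.2 ± 3.01. Tubulin genes are near-identical in sequence, so their separate levels are uncertain. Genes of mature neurons were lower in all 12 of 22 with a row, and 10 fell; Vsnl1 averaged 502 ± 30.0 in SmoM2 and 679 ± 2.25 in WT, and Gabra4 averaged 37.0 ± 1.32 and 50.6 ± 3.54. Scn4b was among the 10 although its groups overlapped, and its limma log2 difference of -0.35 turned to 0.40 without SmoM2 replicate 1 and to 0.26 without WT replicate 1. Fisher's exact test of direction, adjusted over the 6 lists, gave 0.000779 for the young and 0.000659 for the mature list. Both tests include members whose values were seen before the lists were written, so they partly restate what prompted them.

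Genes that glucocorticoid hormones induce were lower in 11 of 12 with a row, out of 18, and 9 fell. Mt2 and Mt1, the metallothionein genes, averaged 109 ± 24.0 and 276 ± 52.5 in SmoM2 and 458 ± 54.1 and 631 ± 58.1 in WT (SD, n = 2 each). Sult1a1 averaged 6.97 ± 0.969 and 18.0 ± 0.834, Fam107a averaged 86.8 ± 5.80 and 193 ± 7.49, and Fkbp5 did not pass. The direction of this list gave an adjusted p of 0.00318 (Fisher's exact test). The list was written after the data were seen and holds Mt2, named above among the lowest genes. Its test thus partly restates what was seen. Of 16 clock genes, 4 had a row and all 4 fell, Hlf, Nr1d2, Clock and Bhlhe40, with an adjusted p of 0.0481 for direction. Without WT replicate 2 the limma log2 differences went from -0.62 to -0.29 for Hlf, from -0.29 to -0.11 for Nr1d2 and from -0.36 to -0.18 for Clock. The labels record no time of day or stress. Of 9 white-matter astrocyte genes, 6 had a row and all 6 rose, with an adjusted p of 0.0396; Myoc averaged 17.8 ± 1.85 in SmoM2 and 6.83 ± 1.13 in WT, and Igfbp2 averaged 138 ± 17.2 and 70.9 ± 2.68, both also genes of meningeal cells. The list median lay 1.06 above WT in SmoM2 replicate 1 and 0.43 in replicate 2, and without replicate 1 the limma log2 differences went from 0.70 to 0.15 for Fbln2, from 0.67 to 0.29 for Vim and from 0.64 to 0.39 for C4b. C4b went to 0.28 and Gfap from 0.53 to 0.32 without WT replicate 2. Gfap and Vim are also members of lists fixed before, so the direction test of the white-matter list partly restates their values.

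The fall of the myelin genes was weighed against 3 explanations. A uniformly smaller share of oligodendrocyte-lineage RNA would lower precursor genes as well. Over the 4 pairings of a SmoM2 with a WT library, the median of the 8 listed precursor genes was 0.328 to 0.458 higher on the log2 scale. The median of the 24 myelin genes lay between -0.970 and -0.695. The listed precursor genes thus did not share the fall. The median of all listed genes was itself 0.251 higher, and 11 of 19 precursor genes, Pdgfra among them, had no row. Those with a row were chosen by their difference, so the test cannot decide for the precursor list as a whole. Less white matter in the SmoM2 pieces cannot be told apart, since only Gfap of the 6 listed white-matter astrocyte genes is not also expressed by meningeal cells; its mean difference over the pairings was 0.532, and it can rise in reactive astrocytes. A delay of maturation that includes neurons remains a candidate explanation: leaving out genes seen before, 11 of 11 young-neuron genes were higher and 8 of 8 mature-neuron genes lower, and the lists differed by 0.663 to 1.07 in the pairings. An action of SmoM2 on oligodendrocyte differentiation, which the design names, stays open and was not tested apart from such a delay.

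Olfactory bulb genes were higher in SmoM2 in all 13 of 14 with a row, and 9 rose. The adjusted p for direction was 0.000779 (Fisher's exact test). That test includes members seen before the list was written, such as Cdhr1 and Ms4a15, so it partly restates what prompted it. Of the 13, 9 had a mean level of at least 1 in WT too, and 7 had groups that did not overlap. Without SmoM2 replicate 1 some limma log2 differences turned negative, from 0.61 to -0.20 for Th and from 0.38 to -0.13 for Sp8. That of Ms4a15 went from 1.63 to -0.12. The list median lay 1.41 above WT in SmoM2 replicate 1 and 0.49 in replicate 2; Cdhr1 read 23.4, 7.58, 4.64 and 4.07 in SmoM2 replicates 1 and 2 and WT replicates 1 and 2, and Ms4a15 read 10.3, 0, 0.18 and 0, but Ntng1 read 14.24, 14.49, 8.99 and 7.68. Olfactory bulb tissue in SmoM2 replicate 1 may account for its excess over replicate 2, and leaves the rise in replicate 2 open: 7 bulb genes not seen before had a median 0.904 higher in replicate 1 than in replicate 2, 6 of the 7 higher, and lay above every one of 10000 random lists of matched level. Uneven carry-over of choroid plexus cannot be told apart from a group difference, since the SmoM2 libraries differed by 0.551 over that list and the nearer of them lay 0.697 from WT, and the same holds for leptomeninges, where libraries of a group differed by up to 0.330 and libraries of different groups by 0.841 to 1.33. Fibroblasts express Pdgfra, so an effect of SmoM2 in them stays open and was not tested.

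Some adjusted p-values in the authors' table are very small for genes whose groups overlap. Gm13841 read 0, 0, 0 and 338 in SmoM2 replicates 1 and 2 and WT replicates 1 and 2, with an adjusted p of 1.29e-108 in the authors' deposited table, and Gm15459 read 0, 493, 0.09 and 0.57, with an adjusted p listed as 0. Overlap occurred in 176 of the 1968 called genes, 8.94%, and in 12 of the 100 and 5 of the 20 genes of smallest p. For 3701 genes with a level of at least 5 in every sample, a standard error was derived from the authors' fold change and p. Its median was 0.109 in the 20% of genes with the lowest replicate SD. In the 20% with the highest it was 0.124, a ratio of 1.14. The median SD went from 0.0444 to 0.257 between these sets, a ratio of 5.79. The deposited p-values may thus carry little of each gene's own observed replicate SD. An SD from 2 samples per group varies widely by sampling alone, and genes were sorted by it. The comparison therefore cannot show that real spread was ignored, and no biological explanation was tested.

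The Y-linked Eif2s3y read 29.6 and 0 in the SmoM2 samples and 0 and 36.0 in the WT samples, and Uty read 0.01, 0.03, 0 and 4.08. WT replicate 2 alone had Ddx3y and lacked Xist, while SmoM2 replicate 1 had Eif2s3y together with Xist. The labels give no sex. Sex may therefore differ between the libraries, and no comparison accounted for it. Fam20c read 35.9 and 40.4 in SmoM2 and 38.3 and 38.4 in WT, while the authors' deposited table gives it a log2 fold change of 0.58.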
